A study of Homo sapiens and Mus musculus with 4 samples.

How the data were processed

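The study profiled binding of TEAD transcription factors, the DNA-binding partners of the co-activator YAP1, by chromatin immunoprecipitation and sequencing (ChIP-seq). The 4 libraries fell into groups of 1: a TEAD and an IgG library from RD, a human embryonal rhabdomyosarcoma cell line, and a TEAD and an input library from YAP-ERMS, mouse cells taken from YAP-driven tumours raised under Myf5-Cre or Pax7-CreER. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sheared by sonication, and barcoded libraries were sequenced on an Illumina HiSeq2000, with the libraries of each cell line barcoded for a single lane. There were no replicates, so no comparison has a replicate error.

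Per the submitters' processing notes, reads were aligned with Bowtie2, and the genome builds were hg19 and mm9. The sequence names in the 2 lists are those of hg19 for RD and of mm9 for YAP-ERMS. The authors deposited 1 peak list per cell line, and the peak names in both are those that MACS writes. The versions, the read filters and the treatment of duplicate reads are not given in the sources used here. The deposited score of each peak is the authors' own value and was read as 10 times the negative log10 of the peak's p-value: the lowest score in both lists is 80, which corresponds to p = 1e-08, the limit that the names of the lists state. The lists' names also state that RD peaks were called against IgG and YAP-ERMS peaks against input. Scores depend on sequencing depth and on the control, so peaks were ranked by score only within a list. Score summaries of the 2 lists are given side by side as values. Common score limits were applied to both lists for the share above 1000 and for the ratio of peak numbers, which carry the same limit. The depth of the 4 libraries is unknown from the files analysed here. The lists hold no summit, read count or fold enrichment.

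From the deposited positions and scores, the following were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Peak width is end minus start in the deposited intervals, and positions are given 1-based. Peaks per Mb were taken over the span from the first to the last peak of a chromosome, because chromosome lengths of these builds were not used here. That span is shorter than the chromosome and includes assembly gaps, so the density over 2 Mb bins holding a peak was computed as well. Intervals on peak numbers are exact Poisson 95% intervals, those on shares are Wilson 95% intervals, and those on medians are from order statistics. All of them cover counting error only and treat peaks as independent, which clustered peaks are not. Spacing was compared with 1000 random placements of each list's peaks on the same sequence between its first and last peak. Clusters were chains of peaks with gaps of at most 12.5 kb. Peaks on Y, random and unplaced sequences counted towards list totals and spacing but not towards the comparison of chromosomes.

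Width at matched score was the log2 of a peak's width minus the median log2 width of the peaks in the same of 50 score bins of that list. Its medians in 2 Mb bins with at least 3 peaks were searched for steps by repeated splitting of each chromosome into parts of at least 5 bins. A step was kept when it reached 0.1 log2 units and its split statistic exceeded those of all 999 shuffles of the bins. Tested on simulated data, made by shuffling the real widths at matched score among the real peaks of each list, this search found 0 steps where none were put in. It recovered 8 of 8 steps of 0.15 log2 units in each list (22630 peaks in RD, 46948 in YAP-ERMS) within 10 Mb, and 8 of 8 steps of 0.3. A single shuffle of each list was used, and steps were put in only near the middle of chromosomes rich in peaks. Steps toward chromosome ends and chromosomes with few peaks were not simulated. The shuffle also scattered very wide peaks that lie together in the RD list. An example is a 2 Mb bin with a median of 1.59 log2 units on chromosome 10. How such bins affect the search was not simulated, so steps on their chromosomes may be missed. Shuffling removes any similarity between neighbouring bins, so slow regional drift can also pass the search.

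The groups, the tests, the rule for named peaks and the alternatives were fixed before the data were examined, except the density over the span, the clusters, the width at matched score and the alternatives so described in the closing section. The planned distances to transcription start sites, the 15 gene lists, the genes shared by both cell lines and the 12 sequence motifs all need an annotation or sequence of hg19 and mm9, and these were not used here. No gene is therefore assigned to any peak. The rule for named peaks without an annotation was the 10 highest scoring peaks of each list by position, with ties broken by width and then by position.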

Results

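TEAD-bound regions were listed for RD, a human embryonal rhabdomyosarcoma cell line, and for YAP-ERMS, mouse cells from YAP-driven tumours. Each list came from 1 TEAD library set against 1 control library of the same cells, IgG for RD and input for YAP-ERMS. There were no replicates, and the differences reported here have no replicate check. The sequencing depth of the 4 libraries is unknown from the files analysed here, so the number of peaks cannot be related to depth.

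The first question was how many regions were listed as bound by TEAD in each cell type and with what scores. The RD list held 22681 peaks that covered 8.61 Mb of hg19. The YAP-ERMS list held 47033 peaks that covered 56.5 Mb of mm9, which is 2.07 times as many peaks and 6.57 times the covered length. The median RD peak was 335 bp wide (interquartile range 250 to 461 bp), and the median YAP-ERMS peak was 1083 bp wide (921 to 1335 bp), which is 3.23 times as wide. The lists differed in species, genome, control and possibly depth and fragment length, so neither ratio measures a difference in TEAD binding between the cell types.

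The scores of both lists began at 80. They depend on depth and control, so the values of the 2 lists are given side by side and a difference between them is not read as one in binding. The median score was 189 in RD (interquartile range 115 to 376) and 205 in YAP-ERMS (121 to 420). A score above 1000 was reached by 1241 RD peaks, or 5.47% (Wilson 95% interval 5.18% to 5.78%), and by 3471 YAP-ERMS peaks, or 7.38% (7.15% to 7.62%). These intervals cover counting error only. In RD, 12 peaks had a score of exactly 3100, as did 97 in YAP-ERMS, so peaks tied at that value were ordered by width. So many peaks at 1 exact value may not be scored on the same scale as the others. The value is not an upper limit, because scores reached 3180 in RD and 3218 in YAP-ERMS. The order among peaks of 3100 or more may therefore not be an order of strength. The 10 YAP-ERMS peaks named below leave out all 97. Scores of 3100 or more were held by 15 RD and 119 YAP-ERMS peaks in all. Higher scoring peaks were wider within each list, where the score is a p-value and not a measure of binding strength. From the lowest to the highest score quintile, the median width went from 205 to 580 bp in RD and from 875 to 1462 bp in YAP-ERMS. Across peaks of 1 list, which are not independent replicates, Spearman's rho between width and score was 0.87 in RD and 0.66 in YAP-ERMS.

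**Figure D1:**
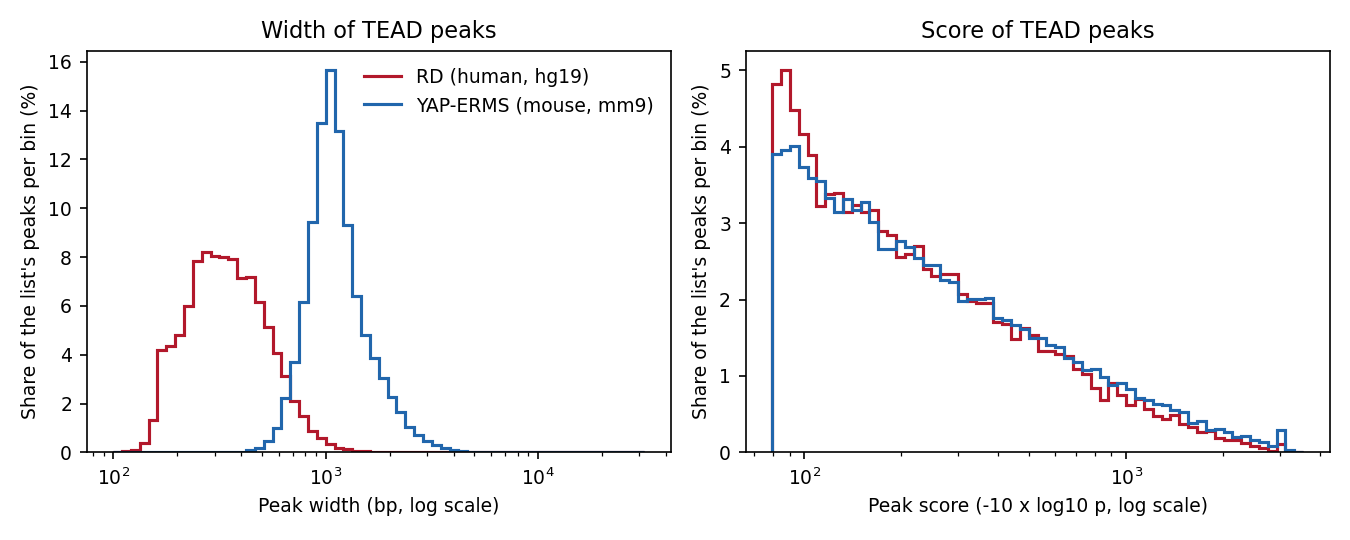
Distribution of the width in bp (left, log axis) and of the authors' score (right, log axis) of TEAD peaks, as the share of each list's peaks per bin, for RD (red) and YAP-ERMS (blue). Median widths were 335 bp and 1083 bp, and the scores of both lists began at 80.

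The highest scoring RD peak lay on chromosome 1 at 118664716 to 118666571 (hg19), was 1856 bp wide and had a score of 3180. It was followed by chromosome 12 at 126821692 to 126823140, with a score of 3111, and by chromosome 7 at 577615 to 578364, with a score of 3104. The other 7 of the first 10 all had a score of 3100 and were ordered by width. They lay on chromosome 5 at 1326852 to 1329166, chromosome 1 at 152080281 to 152082041, chromosome 2 at 227342214 to 227343595, chromosome 9 at 118434772 to 118435883, chromosome 1 at 86072578 to 86073622, chromosome 9 at 114803878 to 114804797 and chromosome 19 at 2540507 to 2541416. Of these 10 peaks, the narrowest was the 750 bp peak on chromosome 7 and the widest was the 2315 bp peak on chromosome 5.

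In YAP-ERMS, the highest scoring peak lay on chromosome 4 at 17090201 to 17091660 (mm9), was 1460 bp wide and had a score of 3218. The next were on chromosome 7 at 117845004 to 117846598, with a score of 3214, chromosome 15 at 81055414 to 81058213, with a score of 3209, and chromosome 15 at 37418011 to 37419635, with a score of 3198. Chromosome 5 at 111633053 to 111635672 had a score of 3189, chromosome 14 at 10290085 to 10293105 a score of 3187, and chromosome 2 at 14233676 to 14235295 a score of 3185. The last 3 of the first 10 were on chromosome 4 at 91837878 to 91839490, with a score of 3175, chromosome 1 at 64872299 to 64874155, with a score of 3165, and chromosome 9 at 34086563 to 34088416, with a score of 3154. The widest of the 10 was the 3021 bp peak on chromosome 14. The genes at these positions were not analysed here.

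The next comparison was between chromosomes within a list. In RD, chromosome 19 had 11.8 peaks per Mb (exact Poisson 95% interval 11.0 to 12.7) and chromosome 2 had 11.7 (11.2 to 12.1), which overlap, and over 2 Mb bins with a peak both had 12.0. Chromosome 13 stood far below the other autosomes, with 251 peaks and 2.67 per Mb (2.35 to 3.02). The next lowest autosome over the span was chromosome 16 with 5.47 (4.995 to 5.97), whose span holds a peak-free stretch of 13.7 Mb, and the median autosome had 8.01. Over 2 Mb bins with a peak, chromosome 13 had 2.99 peaks per Mb and the next lowest autosome was chromosome 3 with 6.03. The X chromosome had 1.82 peaks per Mb (1.62 to 2.05), the lowest of the 23 chromosomes compared. In YAP-ERMS, chromosome 15 led with 27.8 peaks per Mb (26.8 to 28.8), ahead of chromosome 19 with 25.1 (23.8 to 26.4) and chromosome 11 with 24.0 (23.1 to 24.9). Over 2 Mb bins with a peak, chromosome 15 again led with 27.8, and chromosome 11 with 24.97 came before chromosome 19 with 24.3. The median mouse autosome had 18.7, and the lowest, chromosome 14, had 15.2 (14.5 to 15.9). The X chromosome had 5.64 (5.28 to 6.02), so the median autosome was 4.39 times denser than X in RD and 3.32 times denser in YAP-ERMS. Between autosomes, the highest and lowest densities differed 4.42-fold in RD and 1.83-fold in YAP-ERMS. The Poisson intervals treat peaks as independent and are too narrow for clustered peaks. Median scores per chromosome varied less, from 172 to 201 in RD and from 175 to 224 in YAP-ERMS, with X lowest in both lists.

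**Figure D2:**
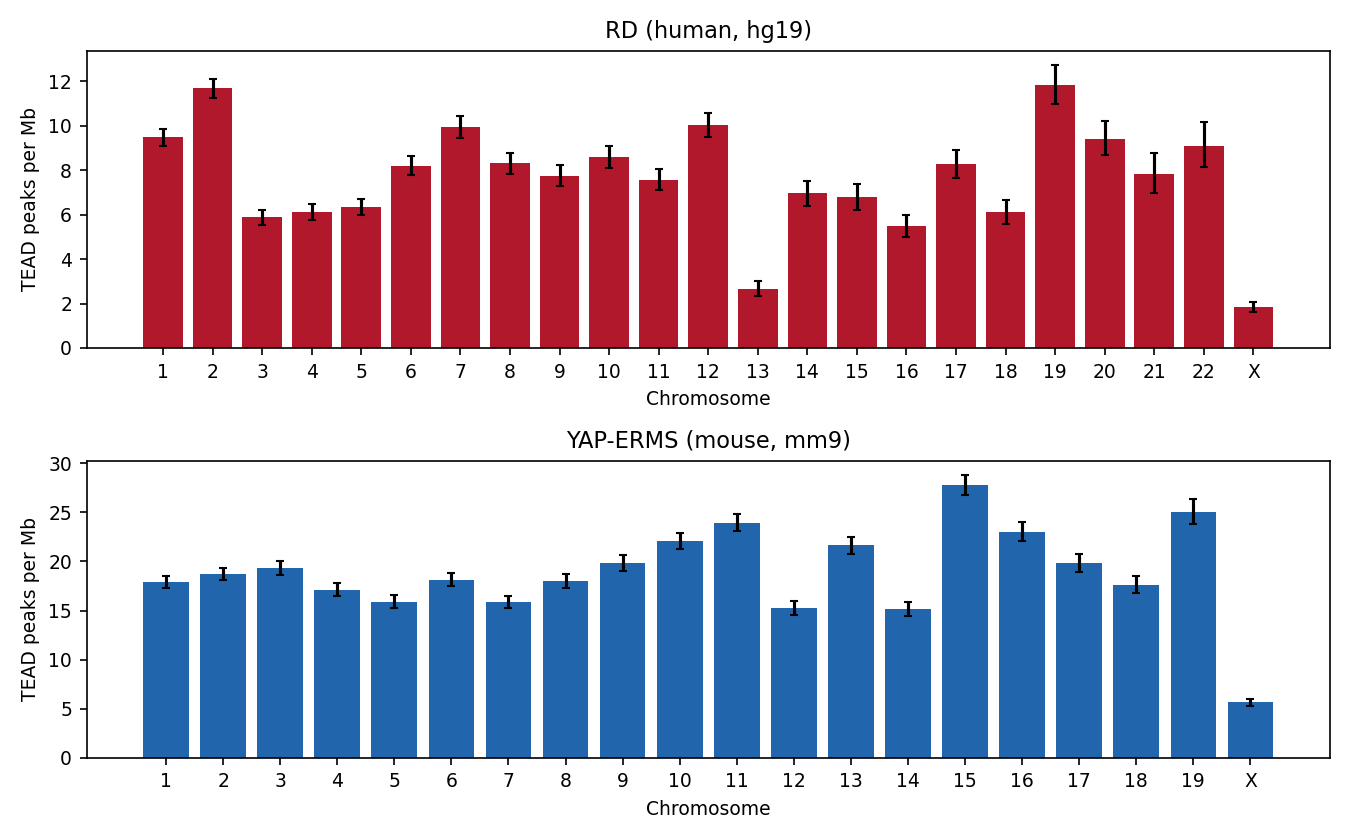
TEAD peaks per Mb on each chromosome of the RD list (top, hg19) and the YAP-ERMS list (bottom, mm9), over the span from the first to the last peak; error bars are exact Poisson 95% intervals. X was lowest in both lists, and in RD chromosome 13 had 2.67 peaks per Mb against 8.01 on the median autosome.

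TEAD peaks were closer together than randomly placed peaks in both cell types. In RD the median gap between neighbouring peaks was 32.7 kb, against 82.9 kb in random placements (range 80.9 to 84.7 kb over 1000 placements). Another peak lay within 10 kb of 46.9% of RD peaks, against 16.2% at random (15.1% to 17.2%). In YAP-ERMS the median gap was 16.7 kb, against 35.0 kb at random (34.5 to 35.6 kb), and 59.1% of peaks had another within 10 kb, against 35.0% (34.3% to 35.9%). Part of this came from broad regions rich or poor in peaks: with each peak moved only within its own 1 Mb bin, the random median gap was 53.3 kb in RD and 25.3 kb in YAP-ERMS, still above the observed gaps. The share with another peak within 10 kb was then 25.4% (24.3% to 26.9%) at random in RD and 44.7% (43.9% to 45.6%) in YAP-ERMS, so the observed share went from 2.90 to 1.85 times the random one in RD and from 1.69 to 1.32 times in YAP-ERMS.

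Clusters of 5 or more peaks with gaps of at most 12.5 kb numbered 350 in RD and held 9.38% of its peaks, against 0.123% in the median of 100 random placements and 0.260% in the highest. In YAP-ERMS there were 1267 such clusters with 17.6% of the peaks, against 1.40% in the median and 1.76% in the highest placement. These placements ran over the whole span from the first to the last peak. Part of the contrast can therefore come from broad regions rich or poor in peaks. Placement within 1 Mb bins was not run for clusters. The following clusters were chosen after their values were seen. The largest in RD held 17 peaks over 85.6 kb on chromosome 2, at 161199295 to 161284890, with a highest score of 942. Next came clusters of 14 peaks, over 69.1 kb on chromosome 9 at 117860863 to 117929923, with a highest score of 2109, and over 63.9 kb on chromosome 8 at 42346393 to 42410297, with a highest score of 1060. On chromosome 4, clusters of 13 and 12 peaks lay side by side at 169445169 to 169506066 and 169525542 to 169587821. The largest in YAP-ERMS held 38 peaks over 172 kb on chromosome 3, at 107490898 to 107662581, with a highest score of 1900. Clusters of 21 peaks each lay on chromosome 9 at 102615879 to 102687199, chromosome 15 at 10593287 to 10722097 and chromosome 2 at 27613639 to 27761564.

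Peak width at a given score also differed between and within chromosomes. Against score-matched peaks of the same list, RD peaks were 11.1% wider on chromosome 2 (0.15 log2 units, 95% interval of the median 0.14 to 0.17) and 7.21% wider on chromosome 7. They were narrower on chromosome 13 (-0.16 log2 units, -0.21 to -0.14) and on X (-0.19, -0.22 to -0.16). In YAP-ERMS, peaks were 11.5% wider on chromosome 15 (0.16 log2 units, 0.14 to 0.17) and 8.88% wider on chromosome 11, and narrower on X (-0.18, -0.20 to -0.16). Chromosomes with wider peaks tended to have more of them, with exceptions such as RD chromosome 22 (9.10 peaks per Mb, -0.08 log2 units) and YAP-ERMS chromosome 13 (21.6 peaks per Mb, -0.04 log2 units). Spearman's rho between width at matched score and peaks per Mb was 0.90 across the 23 RD chromosomes and 0.70 across the 20 YAP-ERMS chromosomes. It was 0.87 and 0.59 without the 2 chromosomes farthest from the median density; chromosomes of 1 library are not independent samples, so no p-value is given.

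Within chromosomes, a search for steps in the width at matched score split 4 chromosomes in RD and 2 in YAP-ERMS, each at 1 place. The search does not tell a single step from slow drift, and a chromosome without a split need not be level. RD chromosome 10, picked after its bins were seen, had no split. Before a 2 Mb bin at 1.59 log2 units, its bins with at least 3 peaks ran from -0.30 to -0.01. Beyond that bin they ran from -0.07 to 0.33. On RD chromosome 2, peaks up to 155820519 had a median of 0.06 log2 units (0.04 to 0.07) and peaks from 156029125 on had 0.27 (0.25 to 0.29). Peaks per Mb went from 9.40 (8.92 to 9.89) to 15.8 (15.0 to 16.6) across the same step. Chromosome 20 went from -0.12 to 0.13 log2 units between 23400958 and 24653435, with 5.68 (4.75 to 6.74) and 12.0 (10.9 to 13.1) peaks per Mb on its sides. Chromosome 9 went from -0.10 to 0.09 between 87992779 and 88357982, with 4.28 (3.86 to 4.74) and 13.6 (12.6 to 14.7) peaks per Mb. The left side of chromosome 9 holds a peak-free stretch of 19.0 Mb, and over 2 Mb bins with a peak its densities were 5.53 and 13.2. Chromosome 6 went from -0.09 to 0.06 between 149957589 and 150030767, with 7.79 (7.34 to 8.25) and 11.1 (9.76 to 12.7) peaks per Mb. In YAP-ERMS, chromosome 4 went from -0.06 to 0.13 between 91893637 and 92012312, with 14.0 (13.3 to 14.8) and 21.5 (20.4 to 22.6) peaks per Mb. Chromosome 15 went from 0.11 to 0.26 between 73569542 and 74419880, with 26.9 (25.7 to 28.1) and 30.8 (28.8 to 32.9) peaks per Mb. Over 2 Mb bins with a peak, its densities were closer, at 27.0 and 29.7. Neither YAP-ERMS chromosome was level beyond its split. Medians of 2 Mb bins on chromosome 15 rose to 0.39 log2 units, fell to 0.06 and rose again to 0.42, and on chromosome 4 they ran from -0.16 to 0.48. A step counted as found again when another search placed one within 10 Mb. All searches used the same list's peaks or a part of them, so they are not independent. The RD steps on chromosomes 2 and 20 were found in each of the 5 other searches run. That on chromosome 20 was placed at 20 Mb over isolated peaks and below the median score, against 24 Mb in the main search. The RD steps on chromosomes 6 and 9 were not found over isolated peaks or over peaks scoring above the list's median. The YAP-ERMS step on chromosome 4 was not found above the median score, and that on chromosome 15 was found again only with 1 Mb bins. Where a call was lost over isolated peaks, the size was 0.15 log2 units on RD chromosome 6, 0.17 on RD chromosome 9 and 0.15 on YAP-ERMS chromosome 15, against 0.15, 0.19 and 0.15 over all peaks. Above the median score it was 0.12, 0.10 and 0.17, and 0.14 on YAP-ERMS chromosome 4 against 0.19 over all peaks.

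**Figure D3:**
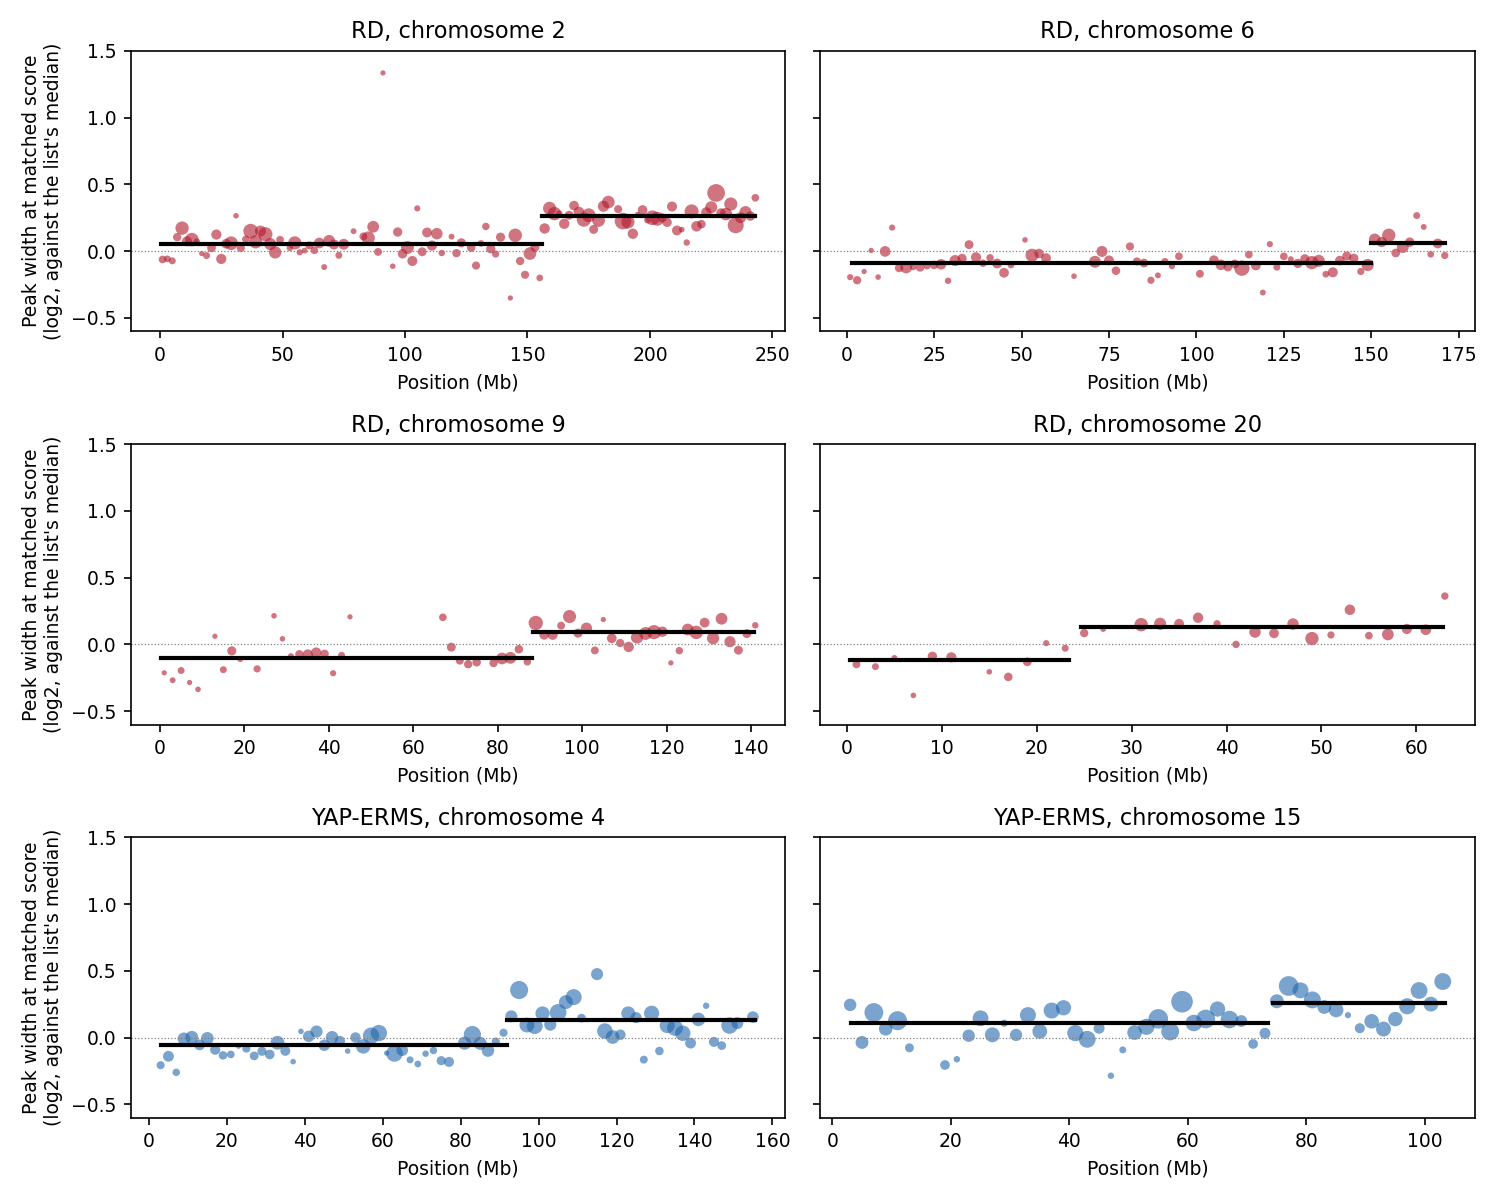
Median peak width at matched score (log2, against the median of the whole list; 0 is the dotted line) in 2 Mb bins along the 6 chromosomes with a step, RD in red and YAP-ERMS in blue; point size grows with the number of peaks in the bin, and black lines are the medians on the sides of each step. On RD chromosome 2 the median went from 0.06 to 0.27 near 156 Mb.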

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

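The tests in this part were chosen after the wide peaks had been seen, except the count of peaks around them, whose prediction was written before that count was made. Peaks on Y, random and unplaced sequences, which the comparison of chromosomes leaves out, numbered 51 in the RD list and 85 in the YAP-ERMS list. They are given because they were present and left out; no count of 0 was predicted for these sequences, so their number tests nothing. In RD their median width was 552 bp against 335 bp over the list, at a median score of 146. In YAP-ERMS their median width was 932 bp against 1083 bp over the list, at a median score of 158.

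The 3 widest peaks of the RD list lay together on chromosome 4, at 49637724 to 49660128 (22.4 kb, score 87.7), 49093173 to 49115148 (22.0 kb, score 1886) and 49148570 to 49158759 (10.2 kb, score 187). In all, 159 RD peaks were over 2-fold wider than the median at their score, and they made up 2.55% of the covered length. Joining of neighbouring peaks stays open: the median number of peaks in the 1 Mb bin of a wide peak was 12, and 14 for all peaks, but joining itself lowers that number and 24 of the wide peaks lay on random or unplaced sequences. Reads piled onto repeats that the build holds in too few copies, beside centromeres or on unplaced sequence, may account for part of them: 32.7% (Wilson 95% interval 25.9% to 40.3%) lay within 2 Mb of the longest peak-free stretch of their chromosome or on random or unplaced sequence, against 2.73% (2.53% to 2.95%) of the other peaks. That is short of the 50% set for this explanation to account for most of them, and the peaks on chromosome 4 did not count because its longest peak-free stretch lies elsewhere. That stretch stood in for the centromere, whose position was not used here. The share may therefore miss such peaks on other chromosomes too, and the shortfall depends on this choice. In YAP-ERMS, 857 peaks were over 2-fold wider than the median at their score, and 1.75% (1.06% to 2.87%) of them lay in such places against 2.71% (2.57% to 2.87%) of the other peaks; the median number of peaks in their 1 Mb bin was 35, and 28 for all peaks. No biological explanation was tested.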

How the results depend on the processing

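Keeping only peaks that score above their list's median left 11340 RD and 23515 YAP-ERMS peaks, as its construction requires; the number of peaks moved by less than 1.5 times when peaks within 1 kb were joined or Y, random and unplaced sequences left out. The alternatives to the ratio of peak numbers, the density of chromosomes and the width steps, and placement within 1 Mb bins, were added after the data were seen. The ratio of YAP-ERMS to RD peaks was 2.07 as deposited, 2.08 with peaks within 1 kb joined, 2.18 at scores of 160 or more and 2.31 at 320 or more; keeping the peaks above each list's median fixes it at 2.07. The random median gap was 2.54 times the observed one in RD and 1.63 times with placement within 1 Mb bins, which keeps the broad differences in density. The 4 width steps in RD became 2 over isolated peaks and 2 over peaks above the median score, on chromosomes 2 and 20 each time. The 2 steps in YAP-ERMS became 1 with 4 Mb bins, 1 over isolated peaks (chromosome 4 both times) and 0 over peaks above the median score. The cause was not tested. With 4 Mb bins RD gained 2 steps, both on chromosome 1. With 1 Mb bins YAP-ERMS gained 1 on chromosome 4 at 117 Mb, and below the median score YAP-ERMS had 2 steps, of which that on chromosome 4 matched and that on chromosome 5 did not. Without an annotation or sequence of hg19 and mm9, the intended alternatives on start sites, gene lists, shared genes and motifs were not run. With 1 library per group no replicate could be left out, and the depth that limits weak peaks is unknown.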

Other observations

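The width steps were found in the data and then tested on the same data, and the comparison of density across the steps was chosen after both had been seen. The predictions for isolated peaks and for low and high scores were written before those values were computed.

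A candidate explanation for the steps in peak width at matched score is copy number of long segments in these tumour cells. More copies may bring more reads behind a peak of a given score, but the lists hold no read counts and this was not tested. Copy number as the cause needs more peaks per Mb on the wider side of each step. That was the case at 100% of the steps, 4 of 4 in RD and 2 of 2 in YAP-ERMS. For joining of neighbouring peaks, the steps over peaks with no other within 20 kb had a median of 0.945 of their size in RD. In YAP-ERMS it was 0.963. That was the outcome predicted if joining was not the cause. However, a joined pair far from others also counts as isolated, and the steps were chosen in a set that holds these peaks. The outcome therefore cannot exclude joining. For uneven matching on score, 100% of the steps in each list had the same sign above and below the median score. That was the outcome predicted if uneven matching was not the cause. The steps were chosen in these same peaks, which favours a shared sign, so the outcome cannot exclude uneven matching. The step was smaller above the median score at 5 of 6 places (RD chromosome 9, 0.10 against 0.26 log2 units). A part that depends on score therefore stays open. Copy number was not measured here and stays open as a hypothesis, as do slow drift in width, which the YAP-ERMS bins beyond the splits do not exclude, and long regions that bind TEAD more often or map reads better, which would also give more peaks per Mb.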
